A study of Homo sapiens with 24 samples.

How the data were processed

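The series mapped N1-methyladenosine (m1A), a methyl mark on adenosine in RNA, in HEK293T cells, a human embryonic kidney cell line. The labels describe 24 libraries in 12 groups of 2 replicates. For wild-type cells (WT) and cells with the ALKBH3 gene knocked out (KO) there were input, anti-m1A immunoprecipitated (IP) and IP plus demethylase libraries. For untreated wild-type cells (UT), cells given 50 µM H2O2 for 30 min (H2O2) and cells kept without serum for 16 h (Starve) there were input and IP libraries. Per the labels' protocols, 40 µg of polyadenylated RNA was taken from 2.5 mg of total RNA, and AMV reverse transcriptase was used at 0.2 mM dNTP. No label says that replicates came from separate cultures, so limma p-values measure only the spread between these samples, which may be technical. Permutation and Fisher's exact p-values rest on counts of regions or genes, and do not measure the spread between replicates.

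The submitters' processing notes name Trim Galore, HISAT and MACS2 and the genome build hg19, without versions or order. Peaks were called with MACS2 for each replicate, per the file headers, giving 10 peak lists, with RefSeq transcripts in place of chromosomes. Coordinates were therefore read as positions on a transcript, although 255 peaks on 4 transcripts lie beyond 110000 nt and may not be such positions. Genomic positions, exons and untranslated regions are not given. The deposited pileup is a coverage signal at the summit, with no visible normalization. The fold enrichment of a peak over its local background is the authors' own value, and was used only to describe, rank or filter peaks within a list. Which input library served as control for each list is not given in the sources used here. The −log10 p-value and −log10 q-value of each peak are also as deposited. The 4 windowed files hold, per the file headers, the coverage of demethylase-treated and IP libraries in windows of 10 nt in steps of 5 nt. The authors had scaled this coverage signal so that the windows of a region sum to about 200. Another deposited column is a score equal to treated minus IP coverage. How the windows were made is not given in the sources used here.

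Lists were assigned to samples by their own names. The descriptions of the untreated libraries point to the starved lists, whereas the file naming gives a separate pair of untreated lists. Inside the UT lists the peak names carry the letters WT, after another prefix than in the WT lists. The file naming was followed, and every comparison with UT rests on it. Gene symbols came from a RefSeq gene table of assembly GRCh38.p14, used for names only: 17019 of 17315 transcripts matched (98.3%), covering 9319 genes. Transcripts of 1 gene repeat the same signal, so counts of regions exceed counts of genes.

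Peaks of the lists in a comparison were merged into regions when they overlapped by 1 nt or more on a transcript. A region was called specific to a group when both lists of that group held it and neither list of the other did. Peak lists hold no value for an uncalled region, so absence means not called, not unmethylated. With 2 lists against 2 no single region can pass 0.05, since the smallest exact p is 0.333. Counts were instead set against 1000 randomisations of the region-by-list table that kept the number of regions per list and of lists per region, giving a two-sided permutation p whose smallest possible value is 0.002. The counts of mixed splits, pairing 1 list of each group, were set beside them. On simulated tables of each of the 4 comparisons, with 200 planted regions, the randomisation separated planted from unplanted counts. The unplanted tables were made by the same randomisation, so this checks the procedure only. It does not show that the randomisation suits real lists, in which isoforms repeat a signal. Comparing UT with WT served as a reference, since both are untreated wild-type cells by the labels.

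The named genes followed a rule fixed before the data were examined: the 12 gained and 8 lost regions with the highest lower fold of the 2 replicates, up to 10 genes of the fixed gene lists, and 6 regions in all lists. Some genes that the rule names are not reported here. The 15 gene lists were also fixed then, and were tested with two-sided Fisher's exact tests over genes with a region in the comparison, adjusted by Benjamini-Hochberg. The design, this rule and most alternative settings were written before the data were examined. The limit of 300 nt for a summit near the 5′ end and that of 110000 nt for far positions were chosen after a first look at the data. Shares carry 95% Wilson intervals, which cover counting error only.

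For the windows, the design fixed beforehand asked for limma on the log2 ratio of treated over IP coverage, with limma on log2 coverage where a file lacked either library. The ratio fit was run first and called 664 of 2922 windows between KO and WT (405 higher, 259 lower; limma, adjusted p under 0.05). Windows with no spread at all then showed that the 2 files of a genotype hold the same treated coverage up to the scaling of each region, within a relative tolerance of 0.001. The ratio fit thus counted 1 treated sample per genotype as 2. After these counts had been seen, the main test was changed to limma on log2(IP coverage + 0.382), and treated over IP was reported as values without a test. The counts of all ratio fits are given with the results or in the closing section. The pseudocount is the 5th percentile of values above 0. On simulated data for this comparison, with 200 of 2922 windows changed, limma recovered 0% at a log2 change of 0.5, 34.5% at 1 and 74.5% at 2. The simulated windows had independent noise and the changed ones were drawn at random, whereas real windows overlap their neighbours. Recovery in the real data may therefore differ.

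The files give no library totals, so depth was read from the number and height of peaks and, in the windows, from values that are whole multiples of 1 step per region in 99.2% to 99.6% of regions (tolerance 0.02 of a step). The alternatives varied the q-value and fold minimum, the overlap rule, the number of peaks per list, transcripts per gene, the pseudocount, low windows, centring, the replicate block and each replicate in turn. Feature shares, a motif test and an alternative without the mitochondrial genome were planned but not run. No genome of the files' build was used here, and no transcript with a mitochondrial symbol was listed. Transcripts without a symbol, among them some of the strongest, were not identified, so mitochondrial signal among them cannot be excluded. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.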

Results

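Peak lists of m1A immunoprecipitation were compared for 5 conditions of HEK293T cells, with 2 replicates each. The lists held 61237 peaks in all. WT lists held 2175 and 3410 peaks, KO lists 3447 and 3524, UT lists 7871 and 9295, H2O2 lists 7459 and 3903, and Starve lists 11362 and 8791. ALKBH3, the targeted gene, had 0 peaks in each of the 10 lists, so the lists cannot check the knockout. The strongest peaks lay on 28S ribosomal RNA, with a pileup of 968016 to 2469560, and on transcripts without a symbol in the gene table, such as NM_001190470. On that transcript the first WT list stood apart, with a fold of 2398 against 215 in the second WT list. The first WT list did so on other transcripts without a symbol too, such as NM_001190702 (537 against 60.8) and NM_001190706 (751 against 58.1). Replicates shared 51.2% of their regions in KO and 21.4% in WT, but 9.42% in UT, 8.79% in Starve and 8.0% in H2O2. Lists of different conditions shared regions too. The second WT list shared 26.3% and 24.4% with the KO lists, and the first WT list 15.0% and 13.5%, all below the 51.2% of the KO replicates. Lists of different conditions among UT, H2O2 and Starve shared 7.05% to 9.59%, about as much as replicates of these conditions.

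The first comparison asked which m1A sites depend on ALKBH3, a demethylase of alkylated nucleic acids. More regions were called in KO alone than in WT alone: 1179 regions of 739 genes lay in both KO lists and neither WT list, and 296 regions of 203 genes in both WT lists and neither KO list. The KO-only regions with the highest folds lay on LUC7L, a splicing factor (22.0 and 24.3 in the 2 KO lists), TMEM70 (20.6 and 19.1), and NDUFB6, a subunit of mitochondrial complex I (19.0 and 21.9). Next came LRPAP1 (14.8 and 15.3), ISYNA1, an enzyme of inositol synthesis (16.5 and 13.9), USP42, a deubiquitinase (12.9 and 11.1), and TPT1 (13.4 and 10.6). The initiation factor EIF5 had folds of 13.2 and 9.47 in its KO-only region, although the gene also had a peak elsewhere in WT. ECHS1, an enzyme of fatty acid oxidation, SSU72, G3BP2, a stress granule protein, and YWHAG completed this group, with lower folds of 9.37, 9.08, 9.06 and 9.05.

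Most of these regions lay near the transcript start, such as nt 10 to 193 of LUC7L (NM_018032), nt 95 to 369 of LRPAP1 (NM_002337) and nt 92 to 347 of TPT1 (NM_001286273). The region of USP42 (NM_032172) lay further in, at nt 2331 to 2538. In WT alone, high folds belonged to WSB2 (21.4 and 27.2), PHF19, a Polycomb-associated protein (18.9 and 20.7), and OBSL1 (19.2 and 16.4). PPP3CB, a catalytic subunit of calcineurin, AMZ2, and the transcription factors TEAD1 and YY1 followed, with lower folds of 11.8, 10.8, 10.7 and 10.3. OBSL1, PPP3CB and YY1 also had a peak in KO, and other transcripts of PPP3CB (such as NM_001289968, nt 36 to 232) had a region in all 10 lists, so its missing KO call concerns 1 transcript. Of the genes with a KO-only region, 622 of 739 had no peak at all in WT, and of those with a WT-only region 149 of 203 had none in KO. Regions in all 4 lists numbered 488, among them 28S ribosomal RNA and FHL1, whose folds were 12.2 and 11.97 in KO and 15.6 and 24.9 in WT.

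Both counts exceeded those of the randomised tables, which gave 456 ± 17.1 KO-only and 204 ± 11.9 WT-only regions (SD over 1000 randomisations; permutation p = 0.002 for each, the smallest possible). Mixed splits of the 4 lists gave at most 228 regions. Of regions in both KO lists 50.02% were in neither WT list, and of regions in both WT lists 30.1% were in neither KO list. Counted by gene, 635 genes were called in KO alone and 194 in WT alone. With peaks of 4-fold enrichment or more the KO-only count was 566, and with 1 transcript per gene the counts were 732 and 189. Leaving out WT replicate 1 turned the order, with 1268 KO-only and 1695 WT-only regions, since a single WT list then sufficed. Without KO replicate 1 the counts were 2026 and 411, without KO replicate 2 they were 1878 and 381, and without WT replicate 2 they were 1780 and 1330.

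Among the fixed gene lists, genes of sterol synthesis had the highest share with a KO-only region, 5 of 10 (FDFT1 and LSS among them) against 18.9% of other genes (Fisher's exact p = 0.0261, adjusted p = 0.639). Other lists gave 4 of 11 chaperones (HSPD1, folds 7.25 and 6.13, and TCP1, 6.99 and 8.77), 7 of 21 cell division genes, 11 of 34 splicing factors and hnRNP proteins, and 3 of 10 histones. The TCP1 region overlapped one called in both UT lists and neither WT list (9.60 and 5.60). INSIG1 of the sterol genes and the splicing factors SF3A1 and SNRNP70 also had a region in UT alone against WT. Counts were 9 of 37 for ribosomal proteins (RPS28, folds 6.12 and 5.93, and RPLP2, 6.21 and 5.69), 4 of 34 for translation factors, and 4 of 16 for oxidative stress genes (PRDX2, a peroxiredoxin, 5.94 and 6.66). They were 2 of 6 for RNA methylation enzymes, of which DNMT1 (8.19 and 9.12) is known as a DNA methyltransferase, 3 of 13 for autophagy genes, 2 of 12 for the integrated stress response, 1 of 8 for serum-responsive early genes and 1 of 6 for DNA repair. The list of mitochondrially encoded genes matched 1 symbol of the gene table. Its 0 genes with a region here do not show that mitochondrial RNA gave no signal. The markers of other cell types also had 0 genes with a region. In WT alone, 2 of 6 RNA methylation genes (ALKBH5 and YTHDF1) had a region, against 5.16% of other genes (exact p = 0.0352, adjusted p = 0.639), and EIF4E2, a cap-binding protein, had folds of 6.91 and 6.72. Over all comparisons 0 of 110 list tests passed adjustment and 7 had an unadjusted p under 0.05.

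**Figure D1:**
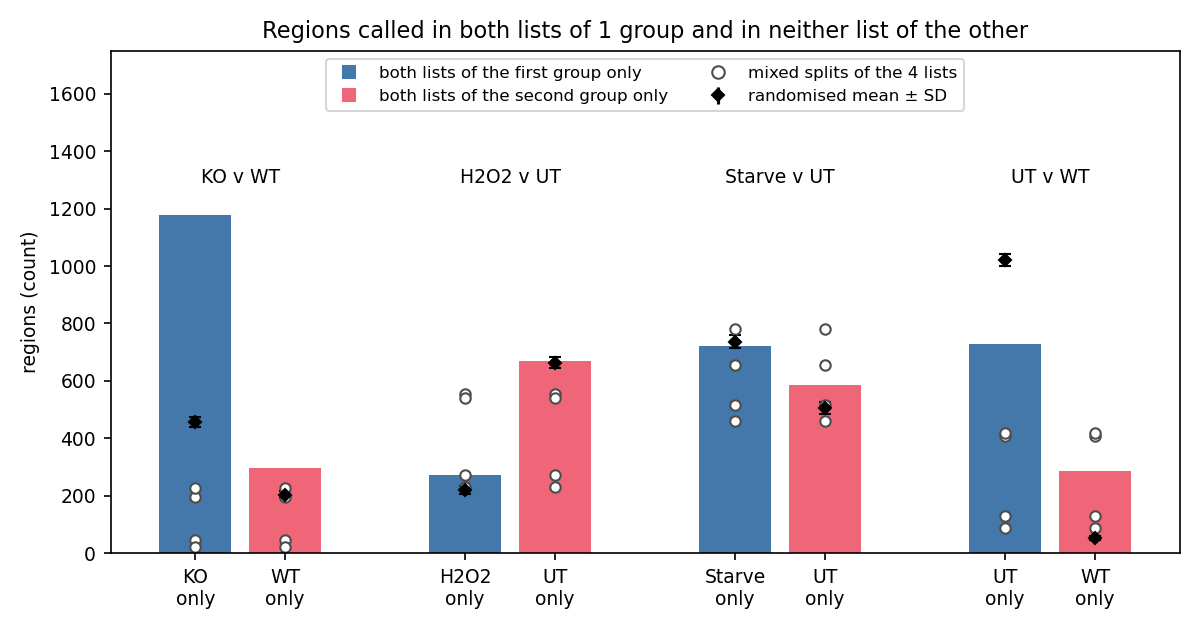
Number of regions called in both lists of 1 group and in neither list of the other (bars), for the 4 comparisons, with the counts of mixed splits (open circles) and the mean ± SD of 1000 randomised tables (diamonds). The KO-only count of 1179 lies above its mixed splits, at most 228. The H2O2-only count of 272 and the Starve-only count of 723 do not exceed theirs, at most 553 and 781. The height of a mixed split also depends on the length of its lists. With the same number of top peaks per list (not drawn), KO-only, H2O2-only and Starve-only counts were 811, 210 and 509, against at most 98, 202 and 500.

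The next comparison asked which sites are gained or lost under oxidative stress. H2O2-only regions numbered 272, on 175 genes, and UT-only regions 669, on 413 genes. The highest folds among the first were on NOP56, a protein of box C/D small nucleolar particles (15.9 and 26.0), IPO13, a nuclear import receptor (16.2 and 14.9), SCAMP4 (14.5 and 24.4), ATG9A, an autophagy protein (13.8 and 11.7), and BRMS1 (11.6 and 19.2). EZR, which links actin to the membrane, ZNF839, DNM1P41, KMT2B, a histone methyltransferase, SCLY, PGAP1 and ADGRL1 followed, with lower folds of 11.5 down to 7.64. Of these 12 genes only ZNF839, DNM1P41 and PGAP1 had no peak elsewhere in UT, and of all 175 genes 75 had none. The initiation factors EIF1 (5.26 and 4.32) and EIF4G3 (3.17 and 3.25) were also in this group, although EIF1 had a region in both WT lists too (5.05 and 4.48).

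UT-only regions with the highest folds lay on CAMTA1 (17.6 and 14.4), SZRD1 (13.1 and 13.3), PRMT5, an arginine methyltransferase (16.0 and 10.9), DCAF7 (14.3 and 10.6), PQBP1 (9.97 and 12.5), the splicing kinase CLK2 (9.52 and 9.04), DDX42, an RNA helicase (9.61 and 8.92), and NDUFA8 (7.80 and 10.4). Of these, SZRD1, DCAF7 and PQBP1 were also called in UT alone against WT, and 218 of the 413 genes had no peak in H2O2. EIF4G1, DDX5, GABARAP, EIF5, RPL17 and RPL10 had UT-only regions with lower folds of 3.81 down to 3.03. So had COL1A1, a fibroblast collagen and the single marker of another cell type with a peak in any list (5.26 and 3.45). Regions in all 4 lists numbered 349, among them MAPK3, a kinase of the growth factor cascade (34.7 and 41.2 in H2O2, 21.8 and 19.0 in UT), and the histone variant H2AZ2.

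The H2O2-only count was above the randomised 220 ± 13.7 (permutation p = 0.002, the smallest possible) but below the largest mixed split, 553, and the UT-only count did not differ from the randomised 663 ± 19.9 (permutation p = 0.785) but was above that split. The split of 553 paired the longer, first H2O2 list with the first UT list. Mixed splits with the shorter, second H2O2 list gave 273 and 230 regions. The true split held 1.14 times as many regions as the larger mixed split, against 5.92 times for KO and WT. With the same number of top peaks per list the UT-only count was 226 and the H2O2-only count 210, both above the largest mixed split of 202. With a fold of 4 or more the UT-only count of 248 was below its largest mixed split, 255. Leaving out an H2O2 list turned the order, since a single list then sufficed: 2665 H2O2-only and 1009 UT-only regions without replicate 1, and 5444 and 811 without replicate 2.

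Serum starvation was compared with the same UT lists. Starve-only regions numbered 723, on 452 genes, and UT-only regions 586, on 344 genes. The highest folds in Starve alone were on FAM3C (13.7 and 16.5), CHMP5, a subunit of ESCRT-III (11.97 and 13.3), NFATC2IP (10.2 and 13.9), KRI1 (9.70 and 13.9), the mitochondrial ribosomal protein MRPL10 (9.39 and 10.4), and GART, an enzyme of purine synthesis (9.39 and 12.02). RBPMS, SKP2, a subunit of a cell cycle ubiquitin ligase, PRR12, PPIL4, the apoptosis gene BAX and ERI3 followed, with lower folds of 9.13 down to 7.73. Of these 12, CHMP5, MRPL10, RBPMS, PPIL4 and BAX had no peak elsewhere in UT. The same held for 173 of the 452 genes, and 131 of the 344 UT-only genes had none in Starve. Of the fixed lists, 5 of 29 cell division genes (CDC20, CDC25A, E2F1, MCM2 and MCM4) had a Starve-only region against 5.30% of other genes (Fisher's exact p = 0.0174, adjusted p = 0.639), and 6 of 47 translation factors did (exact p = 0.0377, adjusted p = 0.639). E2F1 had folds of 7.37 and 15.1, RPS16 6.41 and 8.10, TRMT10C, a mitochondrial tRNA methyltransferase, 5.35 and 5.95, RPL26L1 3.97 and 5.75, EEF1D 4.47 and 3.71, the lysosomal protease CTSD 3.50 and 3.42, and EIF4EBP2 3.33 and 4.45.

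Of the UT-only regions against Starve, CAMTA1, SZRD1, DCAF7 and CLK2 were also among those named against H2O2, which shares the UT lists. DNAJB11, an endoplasmic reticulum chaperone (7.69 and 8.33), AGTRAP (8.34 and 7.62), PHF20L1 (7.98 and 7.38) and NCBP3 (7.35 and 7.26) were also named here, as were the fixed-list genes DDX5 (3.77 and 5.21), COL1A1 and the protease CTSB (12.1 and 3.45). The 1 marker of another cell type, COL1A1, gave an exact p of 0.0406 (adjusted p = 0.639). Regions in all 4 lists numbered 438, among them MPV17L2, a mitochondrial protein (26.1 and 41.4 in Starve, 28.3 and 20.04 in UT). The Starve-only count did not differ from the randomised 737 ± 21.7 (permutation p = 0.527), whereas the UT-only count exceeded 506 ± 20.03 (permutation p = 0.002, the smallest possible). Neither exceeded the largest mixed split, 781, which paired the longer Starve list with the longer UT list. By gene the reverse held: the Starve-only count of 514 exceeded its randomised 473 ± 16.6 (permutation p = 0.0240), and the UT-only count of 345 did not differ from 332 ± 15.2 (permutation p = 0.434). Starve-only regions did exceed the largest mixed split with a fold of 4 or more (362 against 284), with a −log10 q-value of 5 or more (666 against 571) and with the same number of top peaks per list. In the last setting 509 Starve-only and 562 UT-only regions stood against at most 500, so the order turned. It also turned where a single UT list sufficed, with 977 Starve-only and 6820 UT-only regions without UT replicate 1, and 955 and 5551 without UT replicate 2. Neither direction of change is therefore settled.

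H2O2-only and Starve-only regions overlapped in 35 regions of 23 genes, among regions in neither UT list. They included the GDP dissociation inhibitor ARHGDIA (lower fold 6.18), MRPL10 (5.21), NHERF2 (4.39), GYPC (3.78), JAGN1 (3.58) and FBXW5 (3.22). Independent lists of 278 and 730 regions among 20751 would share 9.78 (odds ratio 4.10, Fisher's exact p = 6.65e-11), but 200 randomised tables with the same margins shared 28.9 ± 4.86. The number of lists per region and of regions per list can therefore give most of the overlap. The Fisher's exact p-value is thus no evidence of a shared response to stress. Whether the shared UT lists add to the overlap was not tested. Splitting them would leave 1 UT list per comparison, and was not done.

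UT and WT, both untreated wild-type cells, were compared as a reference without a change of genotype or treatment. UT-only regions numbered 727 and WT-only regions 287. In UT alone were regions of SZRD1, CCM2, a protein of vascular junctions (11.3 and 17.5), DCAF7, the lysosomal membrane protein LAMP1 (10.1 and 11.3), PQBP1, SLC52A2, a riboflavin transporter (9.16 and 14.4), TTC7B (11.4 and 9.08), PKDCC (10.4 and 8.86), RCC1L, SLC7A1 and PGAP6. Fixed-list genes with a UT-only region included TCP1 (9.60 and 5.60), EIF4G1, HNRNPD, LAMP1 and COL1A1, the marker of another cell type. In WT alone were regions of TEAD1, MARCHF9 (9.25 and 18.5), the noncoding CHASERR (8.75 and 12.02), MTHFD1L, a mitochondrial folate enzyme (8.49 and 9.11), AP1S2, IP6K2 and MFGE8.

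Of the translation factors, 5 of 42 (EEF1G, EIF1, EIF3B, EIF4E2 and PABPC4) had a WT-only region against 2.93% of other genes (Fisher's exact p = 0.00780, adjusted p = 0.639). For RNA methylation genes it was 2 of 9, ALKBH5 and YTHDF1 as against KO (exact p = 0.0278, adjusted p = 0.639), and NFE2L2, the regulator of antioxidant genes, had folds of 5.04 and 9.20. The UT-only count was below the randomised 1021 ± 20.3 and the WT-only count above 54.3 ± 7.03 (permutation p = 0.002 for each, the smallest possible). Against the mixed splits, at most 420, the reverse held: the UT-only count was above and the WT-only count below. By gene the UT-only count of 950 did not differ from its randomised 935 ± 16.01 (permutation p = 0.366). The true split held 1.84 times as many regions as the larger mixed split. With the same number of top peaks per list the counts were 101 and 409, so the order turned. It also turned where a single WT list sufficed, to 772 and 1547 without WT replicate 1 and 1060 and 1212 without WT replicate 2.

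Regions called repeatedly lay mostly near the transcript's 5′ end. Among regions in both replicates, the summit was within 300 nt of the start in 83.1% in WT (95% Wilson interval 80.6 to 85.3, n = 983 regions), 76.1% in KO (74.4 to 77.8), 71.7% in H2O2 (68.6 to 74.6), 64.4% in UT (62.0 to 66.8) and 62.3% in Starve (59.9 to 64.6). Regions in 1 replicate alone had lower shares, 57.96% in WT, 63.9% in KO, 32.4% in H2O2, 28.0% in UT and 24.8% in Starve. Over all peaks of a list the share was 55.4% and 73.9% in WT, 72.7% and 71.6% in KO, and 29.2% to 45.0% in the 6 other lists. KO-only regions lay near the 5′ end less often than regions in all 4 lists, 68.5% (65.8 to 71.1) against 86.5% (83.2 to 89.2; Fisher's exact p = 4.19e-15). For WT-only regions the share was 78.4% (73.3 to 82.7; exact p = 0.00398), for H2O2-only 61.0% and for Starve-only 46.6%, against 77.4% and 78.3% in the regions shared by their 4 lists (exact p = 1.36e-05 and 2.78e-27). The UT-only shares were as low, 50.5% against H2O2 and 46.4% against Starve (exact p = 3.66e-17 and 1.06e-25). Transcripts of 1 gene enter these tests as separate regions, so the p-values are too small.

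**Figure D2:**
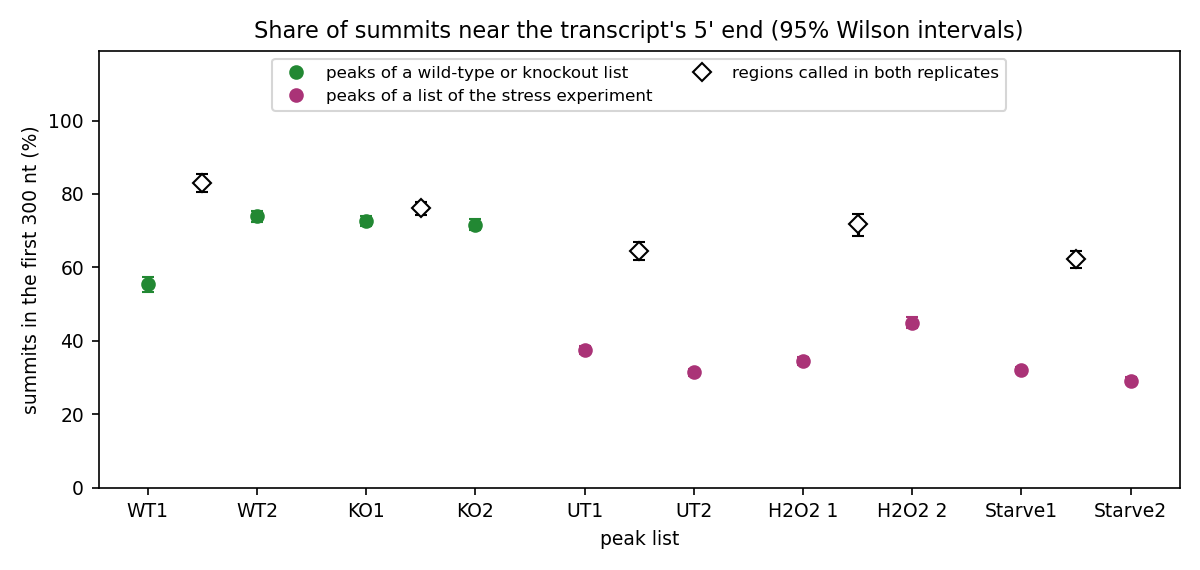
Percent of peak summits within 300 nt of the transcript's 5′ end, for each of the 10 lists (filled points) and for regions called in both replicates of a condition (open diamonds, between the 2 lists), with 95% Wilson intervals. The share in UT is 37.6% and 31.5% per list and 64.4% for regions in both replicates.

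The windowed files compared coverage in IP and demethylase-treated libraries, in which the enzyme removes m1A before sequencing. In WT, treated coverage was higher than IP coverage from 20 to 80 nt on the 5′ side of the summit and lower from 20 to 60 nt on the 3′ side, in both files. At 80 nt on the 3′ side it was lower too, by -0.507 ± 0.271 and -0.0740 ± 0.344. At 100 nt on the 3′ side the differences, 0.185 ± 0.566 and 0.729 ± 0.886, were smaller than their SE. At 120 and 140 nt on that side the files differed in sign. At 40 nt on the 5′ side the difference was 0.230 ± 0.123 and 0.393 ± 0.109 units of region-scaled coverage (SE over 799 and 805 regions), and at 40 nt on the 3′ side it was -0.319 ± 0.177 and -0.694 ± 0.127. In KO it was -0.123 ± 0.0374 and -0.0743 ± 0.0394 on the 5′ side, and 0.241 ± 0.0519 and 0.186 ± 0.0574 on the 3′ side. At 100 nt on the 5′ side treated coverage was higher in both genotypes, by 0.518 ± 0.103 and 1.14 ± 0.698 in WT and by 0.190 ± 0.0253 and 0.133 ± 0.0238 in KO. The 5′ part of a region held 2.56 ± 0.754 and 4.42 ± 0.692 percentage points more of the treated than of the IP coverage in WT, and -0.249 ± 0.248 and 0.0347 ± 0.2503 in KO. Errors are over regions of these files, not over cultures. Transcripts of 1 gene enter as separate regions, so these errors are too small. The first WT file held 799 regions of 540 genes, and the first KO file 2093 of 1274. Both coverages of a region sum to about 200, so a gain in 1 part of a region comes with a loss elsewhere.

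The treated coverage in the 2 files of a genotype was proportional within each region, in 356 of 356 WT and 778 of 778 KO regions, and was counted as 1 sample per genotype. The IP coverage was proportional in 0 of 356 and 0 of 778. The median size of the log2 ratio of treated over IP coverage was 0.43 in WT, over 13270 windows, against 0.26 between the 2 IP replicates. In KO it was 0.23, over 28711 windows, against 0.16. On the 2922 windows of 59 genes listed in all 4 files the sizes were 0.32 and 0.21. Whether the genotypes differ in this ratio was not tested, with 1 treated sample each. The highest coverage per region was lower in treated WT (median 87 steps) than in treated KO (140 and 139).

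**Figure D3:**
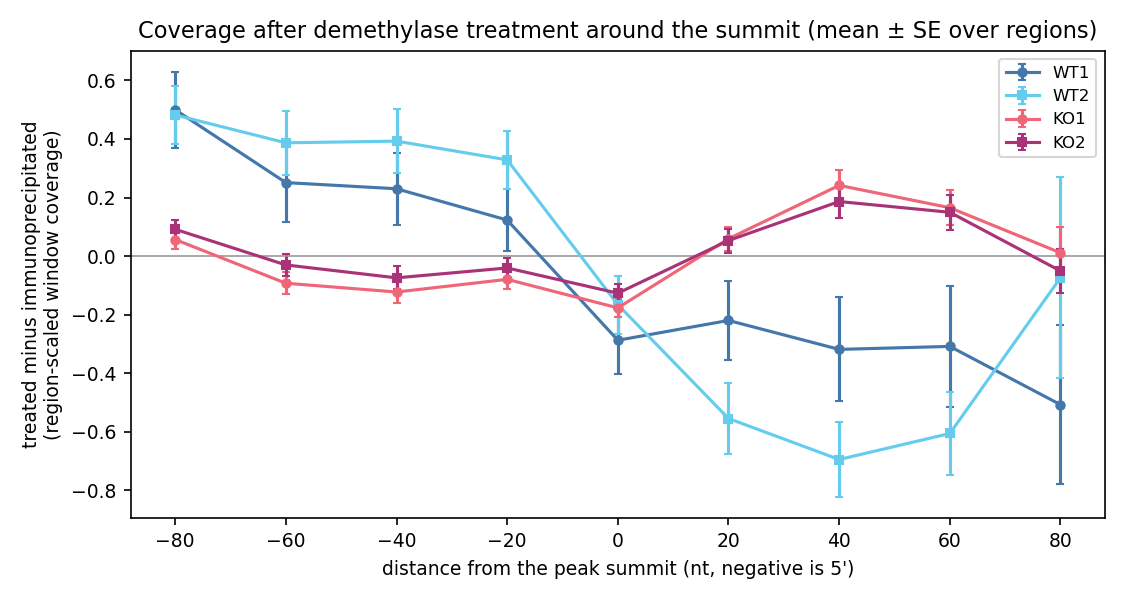
Treated minus IP coverage (region-scaled units) by distance from the peak summit (nt, negative is 5′), as mean ± SE over regions, for the WT and KO files. The treated coverage is 1 sample per genotype, so the lines of a genotype differ by their IP libraries and by the regions of each file. WT lies above 0 from 20 to 80 nt on the 5′ side and below 0 from 20 to 60 nt on the 3′ side, and KO lies between -0.177 and 0.241 over the 80 nt drawn on each side.

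Between KO and WT, IP coverage within shared regions gave 0 of 2922 windows with an adjusted p under 0.05 (limma, 2 against 2), and 186 windows higher and 414 lower in KO at an unadjusted p under 0.05. The excess of lower windows depended on scaling: 304 were higher and 326 lower with each library centred on its median, and 260 and 355 with regions rescaled over shared windows (limma). The smallest adjusted p was 0.185 (limma). Since the windows of a region sum to about 200, a change in the height of a whole region is removed before this test. Only the shape of coverage within regions listed in all 4 files was compared. In the simulation of independent windows, 34.5% of changes were recovered at a log2 change of 1. Thus 0 calls do not show that the shape is the same. The limma fit on the ratio of treated over IP coverage that had been designed beforehand called 664 windows, 405 higher and 259 lower in KO, but treats the single treated sample of each genotype as 2. That fit called 0 windows with a replicate block, 0 without KO replicate 1 or without KO replicate 2, 151 without WT replicate 1 and 410 without WT replicate 2. No window is therefore named.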

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

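The alternatives without far positions, with 1 transcript per gene, with nearest or rescaled windows, and those leaving out replicates of treated over IP coverage were chosen after the data were seen, as was the use of IP coverage alone for the windows. Of 64 alternative counts of group-specific regions, 44 stayed within 1.5 times the main count and 20 did not; of 32 counts without 1 replicate, 12 did and 20 did not. With a fold of 4 or more the counts were 566 KO-only, 172 H2O2-only and 248 UT-only against H2O2, 362 Starve-only and 233 UT-only against Starve, and 286 UT-only against WT, because fewer peaks entered. With 1 transcript per gene they were 732 KO-only and 189 WT-only, 168 H2O2-only and 403 UT-only, 436 Starve-only and 332 UT-only, and 428 UT-only and 190 WT-only, and the stress overlap was 21 regions (randomised 19.1), because isoforms repeat a signal. Counted by gene they were 635 KO-only and 194 WT-only, 345 UT-only against Starve and 105 WT-only against UT. With the same number of top peaks per list, UT-only was 226 against H2O2 and 101 against WT, and the overlap was 17 (randomised 17.9); the cause was not tested. Leaving out 1 replicate each, which asks less of the group left with 1 list, gave 1268 to 2026 KO-only, 381 to 1695 WT-only, 381 to 5444 H2O2-only and 811 to 7520 UT-only, 955 to 8655 Starve-only and 735 to 6820 UT-only, and 772 to 7823 UT-only against WT and 430 to 1547 WT-only against UT, and turned the order at least once in each comparison.

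The numbers of the replicates are not said to mark shared batches, and 2 pairs cannot show it (correlation of same-numbered deviations 0.0377 across windows). With the replicate block the counts stayed at 1179 KO-only and 296 WT-only by construction, and the windows at 0 calls. The IP windows gave 1 call with a pseudocount 10 times smaller, and 0 in every other limma fit of IP coverage, including each left-out replicate. The ratio fit designed beforehand gave 664 calls, and its other settings 577 with a pseudocount of 1, 651 with a pseudocount 10 times smaller, 233 in the higher windows, 693 after centring, 402 with 1 transcript per gene, 2765 of 12534 with nearest windows, and 0 with the replicate block or without either KO replicate. Within genotypes the designed limma test of treated over IP called 1059 of 13270 windows in WT (195 higher, 864 lower) and 0 of 28711 in KO; with a pseudocount of 1 it called 0 and 0, in the higher windows 35 and 0, with 1 transcript per gene 783 and 0, and with no replicate block 4175 and 6519. These fits count 1 treated sample as 2, so none is a replicated test. The median size of the treated over IP log2 ratio was 0.36 in WT and 0.19 in KO with a pseudocount of 1, 0.28 and 0.14 in the higher windows, 0.45 and 0.22 with 1 transcript per gene, and 0.435 to 0.444 and 0.240 to 0.240 without 1 IP replicate. The alternative without the mitochondrial genome, feature shares and the motif test were not run. Library depth is unknown, so a single uncalled region cannot be told from one too shallow to call.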

Other observations

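The test of gene lists among regions in all lists, the test of list length and that of preparations for KO and WT, and the test of unrepeated calls were chosen after the results were seen; the others were written before. Of 38299 regions in any of the 10 lists, 28138 (73.5%) were in 1 list and 93, of 62 genes, were in all 10. Of these 93, 81.7% (95% Wilson interval 72.7 to 88.3) lay within 300 nt of the 5′ end. The highest lower folds among named genes belonged to SPRNP1 (7.52), HEBP1, a heme-binding protein (5.94), TUBB4A, a beta-tubulin (5.89), GTF2IRD1 (4.87), ATP6V0C, a subunit of the vacuolar proton pump (4.48), and the splicing factor SRSF7 (4.30). Splicing factors and hnRNP proteins were the single list past adjustment: 4 of 45 (HNRNPL, PRPF8, SRSF1 and SRSF7) against 0.625% of other genes with a peak (Fisher's exact p = 0.000216, adjusted p = 0.00302 over 14 lists). Expression level, which sets how easily a gene yields a peak, was not accounted for. The members named in all lists also included EIF5A, TYMS and GABARAPL2, 1 gene each of the translation, cell division and autophagy lists.

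KO-only regions outnumbered WT-only regions. Longer KO lists are argued against as the whole cause, since with the same number of top peaks per list the ratio was 2.22. Weak peaks missed in WT stay open. Among regions in both KO lists, 42.4% of the strongest 25% by fold were in neither WT list, above the bound of 25% set beforehand. The reverse direction, 27.6%, was above that bound too. In the weakest 25% of the KO regions the share was 53.5%, and fold in KO does not measure what the WT lists could detect. A difference between preparations stays open, for part or all of the KO-only excess. UT and WT already held 1.84 times as many regions in the true split as in the larger mixed split, against 5.92 for KO and WT. This ratio also depends on how well replicates agree, 9.42% of regions in UT and 51.2% in KO, so it does not alone measure how far preparations part. Against the randomised tables UT and WT differed as well, with 287 WT-only regions against 54.3. Genotype cannot be told apart from preparation, with 2 lists per genotype. The weaker repeat of WT peaks, 21.4% of regions shared between replicates, also stays open. Between single lists of similar length there was little excess. The first KO list held 3447 regions and the second WT list 3409, and they shared 1428. The size of the excess therefore depends on requiring both lists of a group. Lists of similar length must leave similar numbers unshared, so this does not decide the cause. Loss of ALKBH3 remains an untested explanation.

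The lists of the stress experiment had a lower share of peaks near the 5′ end than the WT and KO lists. For UT against WT, calls not repeated in the second replicate are argued against as the whole cause, since in regions of both replicates the UT share was 64.4% (62.0 to 66.8), below the WT interval of 80.6 to 85.3. For H2O2 against KO they stay open, since the share of 71.7% has an interval of 68.6 to 74.6, which overlaps that of KO, 74.4 to 77.8. Longer lists are also argued against as the whole cause. Among the top 2175 peaks of each list the highest share of the 6 lists was 48.1%. This was below the lowest of the WT and KO lists, 55.4% in the first WT list. The cut moved the UT shares from 37.6% and 31.5% to 46.8% and 42.6%. Starve shares went from 32.0% and 29.2% to 48.1% and 27.9%, and H2O2 shares from 34.6% and 45.0% to 39.6% and 44.8%. The second WT list and both KO lists rose too, to 77.6% or more. List length can thus account for part of the gap to the first WT list. The lists also differed in peak length. Peaks of exactly 100 nt made up 50.8% to 57.6% of the UT, H2O2 and Starve lists, and 10.7% to 27.5% of the WT and KO lists. Whether this bears on the share near the 5′ end, or on UT as a reference for WT, was not tested. No biological explanation was tested, and the labels give no batch.

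Treated and IP coverage differed more in WT than in KO. If few distinct molecules in the treated WT coverage were the cause, the excess should vanish in regions with small steps between neighbouring windows. There the ratio of WT to KO was 1.49, against 1.89 over all regions, which lies between the bounds set beforehand for the presence and the absence of this cause, so the explanation cannot be told apart from a genotype difference. With 1 treated sample per genotype, both stay open.

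KO-only regions were in any UT list in 27.8% of cases (25.3 to 30.4), WT-only regions in 64.6% and regions in all 4 lists in 72.8%. The shares were 29.7% for regions in 1 KO list and no WT list, and 33.1% for regions in 1 WT list and no KO list. The summit on 28S ribosomal RNA lay at nt 1376 to 1383 in the WT and KO lists and at nt 1262 to 1266 in the UT, H2O2 and Starve lists. Positions beyond 110000 nt were given for 255 peaks on 4 transcripts.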
